A study of Mus musculus with 4 samples.

How the data were processed

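The deposited values are 1 intensity per probe set and array on a linear scale, made by the authors with MAS5, per the submitters' processing notes. Neither a version nor detection calls are given in the sources used here. Deposited intensities share 1 trimmed mean per array, between 150.07 and 150.08 over the middle 96% of probe sets, as a global scaling by the authors leaves it. Hybridisation, image analysis and summary of probes were not repeated.

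The table holds 22690 probe sets, of which 64 are controls. Of the 22626 others, 20380 have 1 gene symbol in the platform annotation, 691 have several and 1555 have none. The Entrez ids of 20351 probe sets with 1 symbol were found in a gene table of the mouse assembly GRCm38.p6, used for names only, and 0 symbols changed. Older names in the gene lists were matched through the synonyms of that table. No positions are given, since the files name no genome build. A gene was represented by its probe set with the highest mean log2 intensity, and probe sets with several symbols or none were tested but named no gene.

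Each array was scaled to a 2% trimmed mean of 500 over the non-control probe sets, a factor of about 3.35. Probe sets with a mean scaled intensity of at least 100 over the 4 arrays were tested, which kept 13403 and left out 9223. The log2 of scaled intensity plus 50 was fitted with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3, with region as the only term and the 4 arrays as the samples. The total degrees of freedom were 7.43. P-values were adjusted by Benjamini and Hochberg's method over the 13403 probe sets tested, and an adjusted p of at most 0.05 counted as passing. Each of the 8410 genes kept the adjusted p of the probe set that represents it, without a new adjustment over genes. All adjusted p-values are limma's. Fold differences come from the fit and so include the added 50.

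The 28 gene lists, the rule for naming genes, the test and the alternatives listed below were chosen before the data were examined. Lists with at least 5 tested genes (27 of them) were tested with limma's camera with a preset correlation of 0.01, which compares a list with all other genes, and again with the correlation estimated from the residuals. The variance trend was passed to camera to match the fit. This was not fixed beforehand, and camera had first been run without it. Of the 27 lists 13 passed with the preset correlation. With the estimated one 0 passed and 4 had an unadjusted p under 0.05. That form of the test rests on the 2 residual degrees of freedom of the 4 arrays. The named genes are the 14 highest and 14 lowest log2 folds among genes that passed with no overlap of arrays between regions, 11 markers fixed by name, and in each list the 4 largest changes that passed or, where none passed, the 2 brightest genes. This gave 102 genes. Other list members in the text (Irx1, Irx3, Nr2f2, Myl7, Pam, Tek, Robo4, Actc1, Ttn, Col6a2, Col3a1, Col5a2, Vcan, Fbn2, Fn1, Agrn, Hspg2, Cspg4, Col4a1) were chosen after their values were seen, as were the alpha globin probe sets.

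MAS5 values carry no detection call here, so a background was taken from the Bacillus subtilis control probe sets, a choice made after the data were seen. Where both arrays of the dimmer region lay at or below the brightest such control of their array, the fold is given as "at least": the mean log2 of the brighter region, without the added 50, minus the mean over the dimmer region's arrays of log2 of that control. List medians were the same with such genes set to their bound. Levels of different probe sets were not compared.

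The fit was tried on simulated arrays with the real means of the 13403 probe sets, 200 of them changed, in 20 draws. With variances drawn from the fitted prior it recovered 3.13%, 44.5% and 86.3% of the probe sets changed by a log2 fold of 0.5, 1 and 2, and 4.79% of its calls were false. With each probe set's own shrunken variance it recovered 20.7%, 75.7% and 98.6%, and 10.1% of its calls were false, above the 5% aimed at. A planted list of the 25 brightest genes, all shifted by the same log2 fold, was found in 20 of 20 draws under both. Of unchanged lists 2 of 800 and 0 of 800 were called. The simulated errors were independent between genes, so these draws do not test camera's preset correlation.

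Alternatives changed 1 choice at a time: quantile normalisation, median scaling of log2 values, the values as deposited (which leave the scaling between arrays nearly as it was and give the pseudocount and floor more weight), a pseudocount of 1 or 200, no filter or a floor of 300, eBayes without trend, limma's treat with a minimum fold of 1.5, the replicate number as a block, each array left out, the mean of a gene's probe sets, and probe sets ending in _x_at or _s_at left out. The experiment records of the arrays were read for batches only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.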

Results

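Gene expression was measured in 2 regions of the wild-type C57BL/6 mouse heart between embryonic days 10.5 and 11.0. At this stage cushions of mesenchyme form at the atrioventricular (AV) junction, where the valves and septa will arise, while the walls of the ventricles grow as working muscle. Tissue of each region was pooled from about 80 hearts. The pools gave 230 ng of RNA from the AV junction and 250 ng from the ventricular region. Each region was read on a pair of Affymetrix MOE430A arrays, named replicate 1a and 1b, which makes 4 arrays in all. Because they share a replicate number, the arrays of a region were taken as readings of 1 pool, which the sources used here do not state. Setting the AV junction against the ventricular region asks which genes differ between these tissues. It does not separate the cushions from other cells of the junction. Log2 folds are AV junction minus ventricular region throughout, and intensities are mean ± SD over n = 2 arrays after scaling to a common trimmed mean of 500.

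The arrays of a region lay closer to each other than to those of the other region. Across the 13403 probe sets tested, Pearson's r of log2 intensities was 0.981 between the AV arrays, 0.979 between the ventricular arrays, and 0.947 to 0.950 between regions. These correlations are across probe sets, which are not independent replicates. The brightest Bacillus subtilis control, which no mouse RNA should match, read 58.6 and 52.6 on the AV arrays and 97.9 and 104 on the ventricular arrays. Probe sets above that control made up 67.7% and 71.9% on the AV arrays and 62.4% and 59.6% on the ventricular arrays. The 3'/5' intensity ratio of actin lay between 16.6 and 23.4 and that of Gapdh between 15.0 and 18.4. The RNA had been amplified, which shortens transcripts at the 5' end.

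Most genes tested of cushion mesenchyme (17 of 25) were higher in the AV junction, and most of ventricular chamber muscle (16 of 21) were lower. Bmp2, a signal from AV muscle that starts cushion formation, read 1598 ± 237 in the AV junction and 103 ± 50.7 in the ventricular region, an 11.0-fold difference, with 1 of the 2 ventricular arrays above background. Postn, a matrix protein of cushion mesenchyme, read 2283 ± 145 against 451.5 ± 12.2. In the other direction Nppa, a natriuretic peptide of chamber muscle, read 3172 ± 567 in the AV junction and 15470 ± 670 in the ventricular region, and Myl2, the myosin light chain of ventricular muscle, read 13740 ± 1480 against 36470 ± 3050. Transcripts of other tissues moved with region as well. The fetal serum protein gene Afp was at least 48.8-fold higher in the AV junction, and the erythroid gene Hemgn fell to 729 ± 39.9 from 3340 ± 62.7 in the ventricular region.

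Of 8410 genes tested with limma, 712 were higher and 550 lower in the AV junction at a Benjamini-Hochberg adjusted p of at most 0.05, which is 15.0% of them. At least 2-fold differences that passed numbered 173 higher and 123 lower. Over the 13403 probe sets the counts were 970 higher and 882 lower, with 235 and 210 of them at least 2-fold. The median log2 fold over all probe sets was −0.07, and it was −0.21 in the dimmest of 5 equal bins of mean intensity and 0.02 in the brightest. All 1262 genes that passed had arrays of the regions that did not overlap, as had 5246 of the 8410 tested, where chance gives 33.3%. Median scaling of the arrays gave 1208 higher and 286 lower genes and, of probe sets, 1714 and 459, with 78.9% of calls higher against 52.4%. These p-values cover the spread between arrays, taken as 1 pool per region, and not the spread between hearts, and an exact two-sided permutation of 2 against 2 arrays cannot give a p under 0.333. With each array left out in turn, the counts lay between 302 (without ventricular array 1a) and 389 (without AV array 1b) higher genes and between 159 (without ventricular array 1a) and 327 (without AV array 1a) lower ones, and 209 higher and 118 lower genes passed in every such fit.

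**Figure D1:**
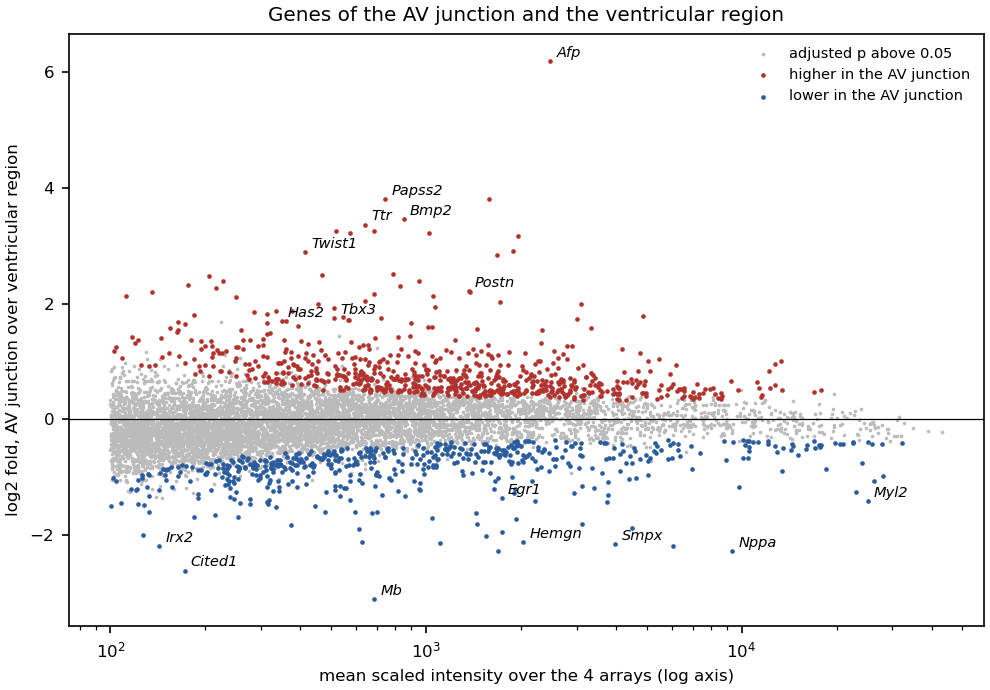
Log2 fold (AV junction minus ventricular region) of each gene against its mean scaled intensity over the 4 arrays on a log axis, with genes higher in the AV junction in red, lower in blue and those above an adjusted p of 0.05 in grey. The 712 higher and 550 lower genes are spread over the whole range of intensity, with Afp, at background in the ventricular region, at a fitted 6.20 and Mb at −3.10.

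Most genes of endocardial cushion mesenchyme were higher in the AV junction. Of the 25 tested genes of a list fixed for this cell type, 17 were higher and 0 lower, while 8 did not pass. Counts adjusted over the list alone were 20 higher and 0 lower. The list's median log2 fold was 1.16, and limma's camera gave an adjusted p of 4.15e-15 with its preset correlation (adjusted p = 0.202 with an estimated correlation). Twist1, a transcription factor of migrating mesenchyme, was at least 7.52-fold higher (765 ± 116 against 62.9 ± 41, adjusted p = 0.00113). Papss2, which makes the sulphate donor for matrix glycosaminoglycans, was at least 14.1-fold higher, and the homeobox gene Prrx1 at least 3.77-fold. Pdgfra, a growth factor receptor of mesenchyme, rose by a log2 fold of 3.23 with an SE of 0.38. Its AV arrays read 2667 and 1128, and its log2 fold was 2.62 without AV array 1a and 3.83 without AV array 1b. Has2, the synthase of the hyaluronan that fills the cushions, rose 3.23-fold (adjusted p = 0.00117). Sox9, a factor of cushion and cartilage cells, did not pass (log2 fold 1.16, adjusted p = 0.0895), and its ventricular arrays differed widely (67.1 ± 63.6, 1 of 2 above background). With 1 array left out the adjusted p of Sox9 ran from 0.0273 (log2 fold 1.75, without ventricular array 1b) to 0.251, and its log2 fold was as low as 0.58 without ventricular array 1a. The hepatic genes Afp and Ttr were higher on the same AV arrays.

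Matrix genes went both ways, more of them higher. Of 45 tested genes of extracellular matrix and hyaluronan, 17 were higher, 4 lower and 24 did not pass, and 20 were higher and 4 lower when adjusted over the list alone. As a list they had a median log2 fold of 0.33 and a camera adjusted p of 1.21e-06 (adjusted p = 0.202 with an estimated correlation). The list shares 11 genes with the cushion list. Postn rose 4.65-fold (adjusted p = 0.000109) and Hapln1, the link protein that ties proteoglycans to hyaluronan, by a log2 fold of 2.04 (adjusted p = 0.000402). The interstitial collagen genes Col6a2, Col3a1 and Col5a2 rose by log2 folds of 1.29, 1.26 and 1.22, the proteoglycan gene Vcan by 1.15, the fibrillin gene Fbn2 by 1.14 and the fibronectin gene Fn1 by 1.05. Second probe sets of Col6a2 and Fn1 gave −0.13 and −0.04 and did not pass. The 4 lower genes were Agrn at −1.11, Hspg2 at −0.82, Cspg4 at −0.72 and Col4a1 at −0.40, and 3 of these, Agrn, Hspg2 and Col4a1, encode proteins of basement membranes. Lower genes that passed numbered 2 without AV array 1a or ventricular array 1a and 1 without AV array 1b or ventricular array 1b. Cspg4 and Col4a1 missed without any 1 of the 4 arrays (adjusted p up to 0.163 and 0.133), and Hspg2 without AV array 1b or ventricular array 1b (up to 0.0783). Among 11 cartilage and tendon genes 3 were higher, 0 lower and 8 did not pass (3 and 0 adjusted over the list alone). They were the collagen gene Col9a3, at least 3.79-fold higher, its partner Col9a1 (log2 fold 1.66, adjusted p = 0.00342) and the transcription factor Sox6 (1.08, adjusted p = 0.0074). A second probe set of Col9a1 gave −0.57 and did not pass. The cartilage list's median log2 fold was 0.36 and camera's adjusted p 0.126, or 0.0198 without ventricular array 1a.

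Some genes that mark the muscle of the AV canal and the later conduction system were also higher. Of 12 tested, 6 were higher, 0 lower and 6 did not pass, with 7 and 0 adjusted over the list alone. Camera's adjusted p was 4.65e-05 at a median log2 fold of 0.82 (adjusted p = 0.202 with an estimated correlation). The T-box repressors Tbx2 and Tbx3, which hold AV muscle back from the chamber programme, were higher. Tbx2 (437 ± 19.5 against 63 ± 10.4) was at least 4.32-fold higher and Tbx3 (819 ± 70.8 against 207 ± 15.5) 3.38-fold (adjusted p = 0.00116 and 0.000783). Msx2, a homeobox target of bone morphogenetic protein (BMP) signals in the canal, rose by a log2 fold of 1.22 (adjusted p = 0.0152, 1 of 2 ventricular arrays above background), with an adjusted p of up to 0.0674 without AV array 1a, AV array 1b or ventricular array 1a. Its relative Msx1, of the cushion list, rose by 1.16 (adjusted p = 0.00775), while a second, dimmer probe set of Msx1 gave −0.65 and did not pass.

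**Figure D2:**
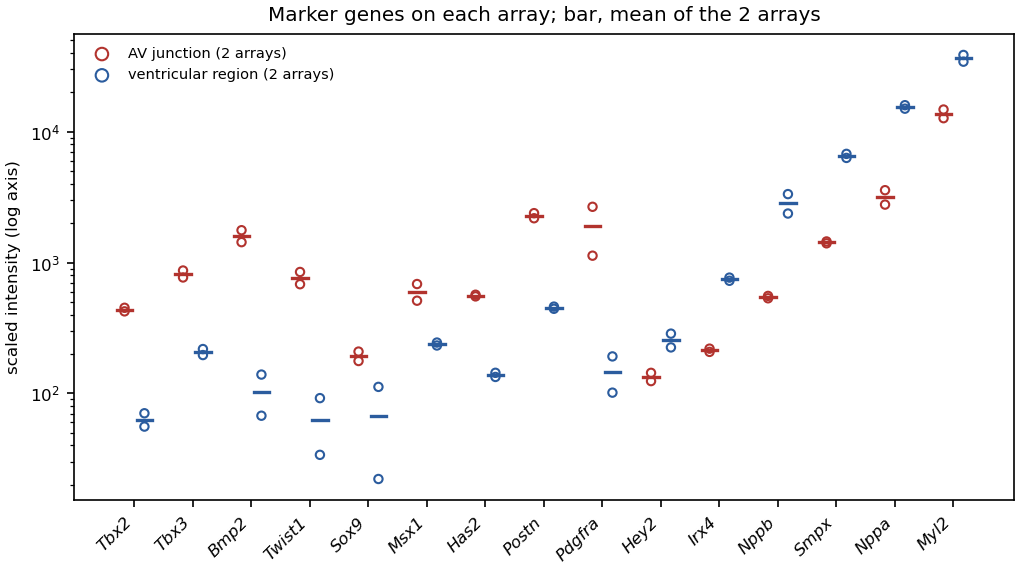
Scaled intensity on a log axis of 15 region and cell type markers, 1 circle per array and a bar at the mean of the 2 arrays of each region. Bmp2, Tbx3 and Postn lie higher on both AV arrays, Nppa, Nppb, Smpx and Myl2 lie higher on both ventricular arrays, and the ventricular arrays of Sox9 are far apart.

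Most components of BMP and TGF-beta signalling tested were higher in the AV junction. Of 31 tested, 18 were higher, 0 lower and 13 did not pass, and 21 were higher and 2 lower when adjusted over the list alone. Their median log2 fold was 0.69 and camera's adjusted p 4.53e-10 (adjusted p = 0.202 with an estimated correlation). Leaving out 1 array gave 11 higher genes without AV array 1a and 12 without each of the others. The list shares 4 genes with the cushion list and 5 with the AV canal list. Tgfb2, a ligand that drives endocardial cells into the cushions, rose 4.59-fold (2296 ± 380 against 458 ± 24.1, adjusted p = 0.000305) on its brightest probe set, while its others gave log2 folds of 0.58 and 0.77 and did not pass (adjusted p = 0.221 and 0.0517). The BMP target Id3 rose by a log2 fold of 1.36 (adjusted p = 0.000638) and the inhibitory Smad gene Smad7 by 1.25 (adjusted p = 0.00389).

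Wnt signalling genes rose in part. Of 22 tested, 6 were higher, 0 lower and 16 did not pass (6 and 1 adjusted over the list alone). The median log2 fold was 0.23 and camera's adjusted p 0.0164, which became 0.126 without AV array 1a (adjusted p = 0.294 with an estimated correlation). The receptor gene Fzd7 rose 5.63-fold (adjusted p = 0.00054, 1 of 2 ventricular arrays above background) and the ligand gene Wnt2 by a log2 fold of 1.92 (adjusted p = 0.000638). Tcf7l1, a nuclear partner of beta-catenin, rose by 0.78 (adjusted p = 0.00452, with 0.32 and no pass on its second probe set), as did the pathway's feedback gene Axin2 by 0.88 (adjusted p = 0.0175). Axin2 reached an adjusted p of up to 0.073 without AV array 1a, AV array 1b or ventricular array 1b. Among 18 Notch genes 3 were higher, 0 lower and 15 did not pass (3 and 3 adjusted over the list alone), and the list did not pass (median 0.10, camera's adjusted p = 0.438). The AV boundary gene Hey1 rose by 1.03 (adjusted p = 0.00418), Maml1 by 0.82 and Notch2 by 0.69. Maml1 gave an adjusted p of up to 0.0564 without AV array 1b or ventricular array 1b, Notch2 of up to 0.0574 without AV array 1a, ventricular array 1a or ventricular array 1b, and second probe sets of both gave −0.10 and −0.52. Hey2, the related repressor of ventricular muscle, did not pass (−0.73, adjusted p = 0.0604).

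Receptors of the ErbB and fibroblast growth factor families went both ways. Of 15 genes 2 were higher, 2 lower and 11 did not pass (2 and 3 adjusted over the list alone), and the median log2 fold of −0.14 turned to 0.01 with median scaling and, over the 6 genes bright enough there, 0.14 with the values as deposited (camera's adjusted p = 0.639). Fgfr2 rose by 1.04 (adjusted p = 0.00386), although its second probe set gave −0.50. Erbb3, the neuregulin receptor of cushion mesenchyme, rose by 0.81 (adjusted p = 0.0334), while Fgfr4 fell by 0.94 (adjusted p = 0.0164) and Egfr by 0.70 (adjusted p = 0.0238). Erbb3 and Egfr reached an adjusted p of up to 0.129 without AV array 1a, AV array 1b or ventricular array 1a, and Fgfr4 of up to 0.0942 without any 1 of the 4 arrays. Second probe sets of Fgfr4 and Egfr gave −0.43 and −0.55 and did not pass.

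Most ventricular chamber genes were lower in the AV junction. Of 21 tested, 0 were higher, 16 lower and 5 did not pass, with 0 and 17 adjusted over the list alone. Across the list the median log2 fold was −1.17 and camera's adjusted p 2.36e-14 (adjusted p = 0.202 with an estimated correlation). Erythroid transcripts were lower in the same arrays. Nppa fell by a log2 fold of 2.28 (adjusted p = 0.000174), Nppb, its partner peptide, by 2.27 (adjusted p = 0.000412) and Smpx, a small protein of striated muscle, by 2.16 (adjusted p = 5.52e-05). Pln, which restrains the calcium pump of the sarcoplasmic reticulum, fell by 2.18 (2123 ± 145 against 9972 ± 2500). The Iroquois genes Irx1, Irx3 and Irx4 fell by 1.69, 1.62 and 1.59. Irx4, which sets ventricular identity, was 3.02-fold higher in the ventricular region (746 ± 29.4 against 213.5 ± 8.57, adjusted p = 0.000979), and Irx2 at least 4.73-fold. Myl2 was 2.65-fold higher there (adjusted p = 0.00054). The co-activator gene Cited1 was at least 5.92-fold lower in the AV junction. The oxygen store gene Mb, which is in none of the lists, was 8.59-fold lower in the AV junction (107 ± 45 against 1266 ± 18.8, adjusted p = 0.000363).

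Genes of the contractile apparatus fell in part. Of 25 sarcomere genes 2 were higher, 12 lower and 11 did not pass (2 and 12 adjusted over the list alone), with a median log2 fold of −0.39 and a camera adjusted p of 1.73e-05 (adjusted p = 0.368 with an estimated correlation). The light chain gene Myl3 fell by 1.07 (adjusted p = 0.00148) and the Z-disc gene Myoz2 by 1.00 (adjusted p = 0.0013), whereas Pdlim3, another Z-disc gene, rose by 1.76 (adjusted p = 0.000536). The count of higher sarcomere genes was 1 without any 1 of the 4 arrays. The cardiac actin gene Actc1 did not pass at −0.18, nor did the titin gene Ttn at 0.03. Among 19 genes of calcium handling, ion channels and gap junctions 1 was higher, 4 lower and 14 did not pass (1 and 4 adjusted over the list alone), and the list did not pass (median −0.25, camera's adjusted p = 0.204). The 1 higher gene was the pacemaker calcium channel gene Cacna1d (log2 fold 1.29, adjusted p = 0.00203). Gja1, the gap junction protein of working muscle, fell by 1.17 (6025 ± 83.8 against 13590 ± 769, adjusted p = 5e-04). The dim potassium channel gene Kcnq1 fell by 0.96 (85.3 ± 10.7 against 213 ± 32.2, adjusted p = 0.0353). Kcnq1 missed with quantile normalisation (limma, adjusted p = 0.0555) and without any 1 of the 4 arrays. Lower genes of this list numbered 2 without ventricular array 1a and 3 without each of the others.

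Most atrial genes that passed were higher in the AV junction. Of 12 tested, 6 were higher, 2 lower and 4 did not pass (7 and 2 adjusted over the list alone). The median log2 fold was 0.50 and camera's adjusted p 0.00505 (adjusted p = 0.368 with an estimated correlation). The atrial potassium channel gene Kcna5 rose 9.55-fold (1279 ± 11.4 against 90.7 ± 29.6, adjusted p = 0.000174), with 1 of 2 ventricular arrays above background. The orphan nuclear receptor genes Nr2f1 and Nr2f2, of which Nr2f2 holds atrial identity, rose by log2 folds of 2.52 and 1.70, and the atrial light chain gene Myl7 by 0.42 (adjusted p = 0.0323, up to 0.161 without any 1 of the 4 arrays). Nppa and the peptide-processing gene Pam were the 2 that fell, and Pam fell by 0.76 (adjusted p = 0.0251, up to 0.109 without AV array 1b or either ventricular array).

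Genes of mitochondrial energy supply were lower in part, as were those of cardiac muscle in general: 12 of 25 sarcomere genes and 7 of 19 cardiomyocyte genes not tied to a chamber were lower. Of 43 oxidative phosphorylation genes 0 were higher, 18 lower and 25 did not pass, with 0 and 27 adjusted over the list alone. Their median log2 fold was −0.33 and camera's adjusted p 1.11e-09 (adjusted p = 0.368 with an estimated correlation). The count of lower genes fell to 8 without AV array 1a, 7 without AV array 1b and 3 without either ventricular array, and it was 6 with median scaling. Uqcrc1 of complex III fell by 1.01 (adjusted p = 0.00143), and the cytochrome oxidase genes Cox4i1 and Cox7a1 by 0.89 and 0.75 (adjusted p = 0.00339 and 0.00562). Cox8b fell by 1.21 (adjusted p = 0.0185, up to 0.106 without AV array 1b, ventricular array 1a or ventricular array 1b). Of 17 genes of fatty acid and ketone oxidation 0 were higher, 2 lower and 15 did not pass (0 and 2 adjusted over the list alone), with a median of −0.21 and a camera adjusted p of 0.0359 (adjusted p = 0.368 with an estimated correlation). That p was 0.111 without AV array 1a, 0.145 with median scaling and 0.0931 without the variance trend. The fatty acid carrier gene Fabp3 fell by 0.74 (adjusted p = 0.00538) and the dehydrogenase gene Acadvl by 0.51 (adjusted p = 0.0322, up to 0.145 without any 1 of the 4 arrays).

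Glycolysis and glucose uptake did not pass as a list. Of 22 genes 1 was higher, 2 lower and 19 did not pass (1 and 2 adjusted over the list alone), and the median of −0.14 turned to 0.02 with median scaling (camera's adjusted p = 0.423). The glucose transporter gene Slc2a3 rose by 0.85 (adjusted p = 0.00321). The muscle enolase gene Eno3 fell by 0.73 (adjusted p = 0.0205, up to 0.0896 without AV array 1a, ventricular array 1a or ventricular array 1b) and the hexokinase gene Hk1 by 0.54 (adjusted p = 0.0137, or 0.0818 without ventricular array 1a), with −0.29 and no pass on the second probe set of Hk1. Without AV array 1b 2 genes of the list were higher. Of 29 ribosomal protein genes 0 were higher, 6 lower and 23 did not pass, with 0 and 8 adjusted over the list alone. Their median was −0.24, and camera's adjusted p was 9.14e-05 (adjusted p = 0.202 with an estimated correlation). The median was −0.08 with median scaling, and lower genes numbered 4 without AV array 1a, 3 without AV array 1b, 2 without ventricular array 1a and 1 without ventricular array 1b. Rpl12 fell by 1.30 (adjusted p = 0.00228). Rpl37, Rps25 and Rps27l each fell by 0.60, and leaving out 1 array ended these calls: any of the 4 for Rpl37 (up to 0.199), AV array 1b or either ventricular array for Rps25 (up to 0.0876), and ventricular array 1b for Rps27l (0.0584).

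Endothelial and endocardial genes did not pass as a list. Of 21 genes 4 were higher, 2 lower and 15 did not pass (4 and 4 adjusted over the list alone), with a median log2 fold of 0.16 and a camera adjusted p of 0.157. Klf4, a factor induced by blood flow, rose by 1.71 (adjusted p = 0.000658), Nfatc1, which marks the endocardium of the cushions, by 1.38 (adjusted p = 0.00682) and Sox17 by 1.12 (adjusted p = 0.00781). Second probe sets of Klf4 and Nfatc1 gave 0.31 and 0.41 and did not pass (adjusted p = 0.429 and 0.287). The receptor gene Tek rose by 0.98 (adjusted p = 0.00935, or 0.0547 without ventricular array 1a). Egfl7, a secreted protein of vessels, fell by 1.09 (adjusted p = 0.0089), and the guidance receptor gene Robo4 fell by 0.79 (adjusted p = 0.0257, up to 0.114 without any 1 of the 4 arrays).

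Many erythroid genes were lower in the AV junction. Of 16 erythroid genes 0 were higher, 11 lower and 5 did not pass, with 0 and 14 adjusted over the list alone. Across the list the median was −0.89 and camera's adjusted p 4.53e-10 (adjusted p = 0.202 with an estimated correlation). The count of lower genes was 8 with median scaling, 7 without either ventricular array, 8 without AV array 1a and 9 without AV array 1b. Hemgn, a nuclear protein of red cell precursors, fell by 2.12 (adjusted p = 9.96e-05), the haem synthesis gene Alas2 fell by 1.89 (adjusted p = 0.00186), the anion exchanger gene Slc4a1 fell by 1.87 (adjusted p = 0.000148) and the embryonic globin gene Hba-x fell by 1.80 (adjusted p = 0.000109). Probe sets shared by the adult alpha globin genes, which name no single gene, gave log2 folds from −2.60 to −2.32. Of 7 macrophage and platelet genes 1 was higher, 1 lower and 5 did not pass (1 and 2 adjusted over the list alone), and the median of −0.22 turned to 0.09 with quantile normalisation (camera's adjusted p = 0.934). The macrophage gene Lyz2 fell by 1.37 (adjusted p = 0.00482). The growth factor receptor gene Csf1r rose by 1.11 (adjusted p = 0.00162), and its second probe set gave −0.45.

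Some endoderm, lung and liver genes were higher in the AV junction. Only 5 of the list were bright enough to test, of which 3 were higher, 0 lower and 2 did not pass (3 and 0 adjusted over the list alone). The median was 1.25 and camera's adjusted p 0.000246 (adjusted p = 0.202 with an estimated correlation). Afp read 4939 ± 388 in the AV junction and 17.9 ± 1.19 in the ventricular region, where it was at background. On this brightest probe set Afp was at least 48.8-fold higher (adjusted p = 3.12e-06). Its other tested probe sets gave fitted log2 folds of 3.95 and 5.08. Ttr, a carrier of thyroid hormone made by liver and yolk sac, was at least 12-fold higher on its brightest probe set (1209 ± 60.2 against 74.3 ± 32.5, adjusted p = 0.000246). Its second probe set gave a fitted log2 fold of 2.125. Alb, the serum albumin gene, rose by 1.25 (378 ± 66.8 against 129 ± 15.4, adjusted p = 0.00905, or 0.0538 without AV array 1a).

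Lists of the other cell types of the heart did not pass. Of 13 epicardial genes 1 was higher, 2 lower and 10 did not pass (1 and 3 adjusted over the list alone), and the median of −0.10 turned to 0.06 with median scaling (camera's adjusted p = 0.658). The retinal dehydrogenase gene Aldh1a1 rose by 0.59 (adjusted p = 0.0228), and the keratin genes Krt19 and Krt18 fell by 0.85 and 0.64 (adjusted p = 0.023 and 0.0176). Each of these 3 calls was lost with 1 array left out: Aldh1a1 without AV array 1b or either ventricular array (up to 0.094), Krt19 without either AV array or ventricular array 1a (up to 0.128), and Krt18 without AV array 1a or either ventricular array (up to 0.0921). Of 9 smooth muscle genes 0 were higher, 1 lower and 8 did not pass (0 and 2 adjusted over the list alone), and the median of −0.06 turned to 0.10 with median scaling (camera's adjusted p = 0.586). The 1 lower gene was Tagln, which binds actin (−0.98, adjusted p = 0.00637). Of 6 neural crest genes 1, Erbb3, was higher, 0 lower and 5 did not pass (1 and 0 adjusted over the list alone, median 0.27, camera's adjusted p = 0.423). Erbb3 lost its call without either AV array or ventricular array 1a (up to 0.129). Of 7 genes of the second heart field and outflow tract limma called 0 higher and 0 lower, also when adjusted over the list alone, and 0 higher and 1 lower at an unadjusted p under 0.05. That list's median of −0.20 turned to 0.05 with the values as deposited, where only 2 of the 7 were bright enough to test (camera's adjusted p = 0.562). Mef2c, a muscle factor, gave 0.13 (adjusted p = 0.459) and Gata4, a cardiac factor of both regions, −0.04 (adjusted p = 0.876).

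Proliferation genes gave few calls between the regions. Of 27 tested, 1 was higher, 0 lower and 26 did not pass (0 and 0 adjusted over the list alone, 5 higher and 4 lower at an unadjusted p under 0.05 in limma). With median scaling 5 were higher and 0 lower, with a median of 0.17. The median of 0.01 turned to −0.01 with quantile normalisation (camera's adjusted p = 0.562). Tpx2, a spindle protein gene, rose by 0.74 (adjusted p = 0.0285, up to 0.109 without either AV array or ventricular array 1b), and its second probe set gave −0.20. Of 17 cyclins and cell cycle inhibitors 2 were higher, 3 lower and 12 did not pass (2 and 3 adjusted over the list alone), and the median of −0.04 turned to 0.12 with median scaling (camera's adjusted p = 0.934). Lower genes numbered 2 without AV array 1b and 1 without each of the others. Gas1, a membrane protein gene of resting cells, rose by 1.22 (adjusted p = 0.00116), with −0.22 from its second probe set. The D-type cyclin gene Ccnd1 rose by 0.56 (adjusted p = 0.00959, or 0.0609 without ventricular array 1a). The inhibitor gene Cdkn1c fell by 0.89 (adjusted p = 0.00219) and Cdkn2d by 0.82 (adjusted p = 0.0272, up to 0.114 without AV array 1a or either ventricular array).

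Some early response genes fell in the AV junction. Of 19 immediate early and heat shock genes 2 were higher, 4 lower and 13 did not pass (2 and 6 adjusted over the list alone). The median of 0.08, which turned to −0.06 over the 12 genes tested with the values as deposited, and the mean of −0.09 differed in sign, and camera ranked the list lower without passing (adjusted p = 0.856). The count of higher genes was 1 without AV array 1a and 0 without AV array 1b or either ventricular array, against 5 at an unadjusted p under 0.05 in limma with all arrays. Egr1, a factor switched on by growth signals, fell by 1.36 (adjusted p = 5e-04), the secreted matricellular gene Ccn2 by 1.15 (adjusted p = 0.00109) and Fos by 1.06 (adjusted p = 0.00476). Atf3, a stress factor in the same list, gave −0.82 (adjusted p = 0.04, up to 0.152 without AV array 1a or either ventricular array). The sex-chromosome transcripts did not pass on their brightest probe sets: Xist gave −0.16 (adjusted p = 0.282) and Eif2s3y 0.13 (adjusted p = 0.66). Other probe sets of Xist gave −0.16 (adjusted p = 0.531) and −0.58, and the latter passed (adjusted p = 0.0499). By brightest probe set 0 of 4 genes passed in limma or at an unadjusted p under 0.05, and their median of −0.03 turned to 0.13 with quantile normalisation.

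**Figure D3:**
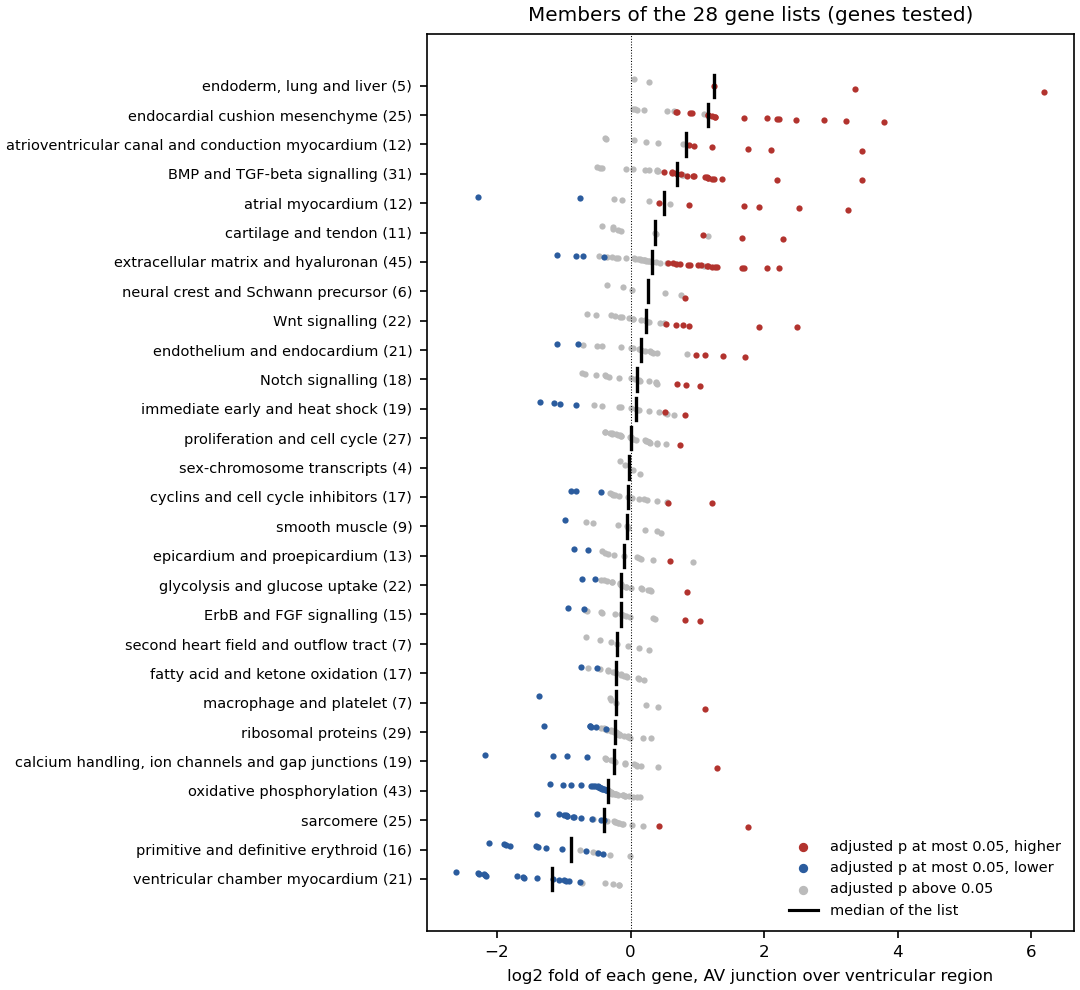
Log2 folds (AV junction minus ventricular region) of the tested members of the 28 gene lists, 1 point per gene, with a black bar at each list's median. Medians run from −1.17 for the ventricular chamber to 1.16 for cushion mesenchyme and 1.25 for the 5 endoderm, lung and liver genes, and those of the epicardial, smooth muscle, glycolysis, cyclin, ErbB and FGF, and sex-chromosome lists change sign with median scaling.

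Several of the largest differences lay outside these lists. The cell adhesion gene Ncam1 read 2995 ± 27.2 in the AV junction and 169 ± 31.7 in the ventricular region, a log2 fold of 3.81 (adjusted p = 3.48e-05), and its second probe set gave 1.22 (adjusted p = 0.0096). The calcium sensor gene Vsnl1 was at least 9.66-fold higher on its brightest probe set, while its second gave a log2 fold of 0.51 and did not pass (adjusted p = 0.257). Shisa2, an inhibitor of growth factor and Wnt receptors, was at least 10.6-fold higher on its brightest probe set, and its second gave a fitted log2 fold of 2.42. The carbonic anhydrase gene Car3 rose 8.94-fold (3562 ± 178 against 354 ± 0.802), and Cav1, which forms caveolae, by a log2 fold of 2.91 (adjusted p = 5.52e-05). Kitl, the ligand of the Kit receptor, rose by 2.84 (adjusted p = 0.000397), while its other probe sets gave 0.56 and −0.13. Among the genes that fell were Tm4sf1, a surface protein (−2.13, adjusted p = 0.000192), Tmem71 (−2.11, adjusted p = 0.000692) and Retreg1, a receptor for the turnover of endoplasmic reticulum (−1.95, adjusted p = 0.000397). The second probe set of Retreg1 gave −1.05 (adjusted p = 0.0152). Prr15 was at least 4.13-fold lower. The collagen receptor gene Ddr1 gave −2.02 (adjusted p = 0.000889) on its brightest probe set and −0.52 to 0.16 on its 5 others. Without ventricular array 1a or 1b another probe set of Ddr1 was the brightest, and it gave −0.19 and −0.20 (adjusted p = 0.643 and 0.603).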

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

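Using the second brightest probe set, leaving out erythroid and hepatic genes, and the bound from Bacillus subtilis controls were tests chosen after the data were seen. Median scaling moved the median log2 fold of all probe sets from −0.07 to 0.09 and gave 1714 higher and 459 lower probe sets (78.9% of calls higher against 52.4%), 137 lower ones at least 2-fold, and 1208 higher and 286 lower genes, all 286 among the 550. Within lists it gave 5 higher proliferation genes (1 before), 4 higher immediate early genes (2 before), and lower genes numbered 6 in oxidative phosphorylation (18 before), 3 in ribosomal proteins (6 before) and 2 in matrix (4 before). The values as deposited, where the same pseudocount and floor weigh more, left 7120 probe sets and gave 110 higher and 86 lower at least 2-fold. A pseudocount of 200, which shrinks dim folds, gave 115 and 83. Without a filter, which adds dim probe sets, 580 and 431 probe sets and 438 and 269 genes passed. A floor of 300 gave 138 lower ones at least 2-fold. Without trend 326 and 343 probe sets and 243 and 209 genes passed (the cause was not tested). Requiring a fold above 1.5 (treat) left 91 and 60 probe sets and 68 and 34 genes. With the replicate block 1375 lower probe sets and 852 lower genes passed, 1344 probe sets were higher, and the cartilage list passed (adjusted p = 0.0396). The numbers 1a and 1b do not pair the arrays, whose deviations correlated across probe sets at 0.0564.

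Leaving out 1 array, where the lone array is assumed to vary like the other region's, gave 402 to 534 higher and 254 to 522 lower probe sets, and 302 to 389 higher and 159 to 327 lower genes. The fits then rest on fewer arrays. Over these fits camera's adjusted p lay between 0.0198 (without ventricular array 1a) and 0.129 for the cartilage list, 0.0103 and 0.126 (without AV array 1a) for Wnt, and 0.0213 and 0.111 (without AV array 1a) for fatty acid oxidation. The fatty acid list also missed at 0.145 with median scaling and 0.0931 without trend. With an estimated correlation, on 2 residual degrees of freedom, 0 lists passed: the adjusted p was 0.202 for the cushion, AV canal, chamber, erythroid, endoderm, matrix, BMP and ribosomal lists, 0.294 for Wnt, and 0.368 for the atrial, sarcomere, oxidative phosphorylation and fatty acid lists. In the other alternatives 11 to 14 lists passed.

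Of the 548 genes that passed on the brightest of 2 or more probe sets, 424 had the same sign on the second brightest and 130 also passed there. Among the 103 of them that differed at least 2-fold, 76 had the same sign and 39 also passed. Of 2652 genes with a second probe set, 145 were higher and 129 lower on it, of which 71 and 59 also passed on the brightest. Of the 35 named genes that have one it reversed 8, none of which passed on it, and ended the calls of 10 others, Vsnl1 0.51, Kitl 0.56, Ddr1 −0.20, Klf4 0.31, Nfatc1 0.41, Tgfb2 0.58, Tcf7l1 0.32, Fgfr4 −0.43, Egfr −0.55 and Hk1 −0.29. The reversed genes were Msx1 −0.65, Csf1r −0.45, Col9a1 −0.57, Maml1 −0.10, Notch2 −0.52, Fgfr2 −0.50, Tpx2 −0.20 and Gas1 −0.22. Leaving out probe sets ending in _x_at or _s_at reversed 3 of those 8 alike (Msx1, Maml1, Fgfr2). The cause was not tested. Of the 102, 48 missed with treat, 17 without trend, 14 without a filter, 8 with the mean of probe sets, 5 with median scaling, 2 with quantile normalisation and 14 to 19 with 1 array left out (100 of them had a value without ventricular array 1a). Sox9 passed with median scaling (0.0492) and the replicate block (0.0261), and its log2 fold was 1.75 without ventricular array 1b. Hey2 passed with the replicate block (0.0431) and the mean of probe sets (0.0489). That last fit was adjusted over genes instead of probe sets, and Hey2 has only 1 tested probe set. With erythroid and hepatic genes taken out of the finished calls, without a new fit, 706 genes were higher and 529 lower. Camera run on the remaining genes passed 11 of 25 lists. These counts could not show whether carried-over tissue affects the other genes. A batch block was not run, since each array had its own fluidics module and all 4 shared 1 chip lot, station and day. Treat was not computed for the count of at least 2-fold differences. Dim probe sets gave fewer calls: in 5 equal bins of mean intensity 92 passed in the dimmest and 742 in the brightest. From the dimmest bin up, lower and higher calls numbered 55 and 37, 105 and 76, 182 and 150, 199 and 306, and 341 and 401. The brightest Bacillus subtilis control read higher on the ventricular arrays, and whether such an offset adds to the dim lower calls was not tested. The median SE was 0.262 in the dimmest bin and 0.105 in the brightest, and the cause was not tested.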

Other observations

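The tests of growth factor, axon guidance, Hox, hepatic, further erythroid and general cardiomyocyte genes, and the 3 tests of scaling, were chosen after the results were seen. Bootstrap intervals of list medians resampled the genes of a list as if independent, and cover neither the spread between arrays nor that between hearts.

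Some insulin-like growth factor genes rose in the AV junction. Of 15 tested, 5 were higher, 1 lower and 9 did not pass, with 6 and 2 adjusted over the list alone. The median log2 fold was 0.24 and camera's adjusted p 0.00557 (adjusted p = 0.562 with an estimated correlation). The ligand gene Igf1 rose by 1.99, the binding protein genes Igfbp5 and Igfbp7 by 2.04 and 1.29, the protease gene Htra1 by 1.94 and the receptor substrate gene Irs1 by 0.82, while a second probe set of Igfbp5 gave 0.33 and the receptor gene Igf1r fell by 0.82 (adjusted p = 0.0445, up to 0.173 without any 1 of the 4 arrays). The list was made after Igf1 was seen to rise, and that gene counts towards its result.

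Axon guidance genes went both ways by region. Of 27 tested, 5 were higher, 5 lower and 17 did not pass (5 and 8 adjusted over the list alone, median −0.13, camera's adjusted p = 0.562). The netrin receptor genes Unc5c and Unc5b rose by 1.19 and 0.58, the semaphorin receptor gene Plxnc1 by 1.12, the ephrin receptor gene Epha7 by 0.91 and Robo1 by 0.87. Another probe set of Epha7 gave −0.80 and did not pass. Slit2, a ligand of Robo receptors, fell by 1.73, the semaphorin gene Sema4d by 1.11, the netrin gene Ntn1 by 0.94, Robo4 by 0.79 and Plxna3 by 0.51. Of these, Plxnc1 and Slit2 passed with each array left out in turn. The others missed without ventricular array 1a (Sema4d, 0.079), AV array 1b or ventricular array 1b (Unc5c, 0.103), AV array 1a or ventricular array 1b (Epha7, 0.0668), AV array 1b or either ventricular array (Unc5b, up to 0.0746), AV array 1a or either ventricular array (Ntn1, up to 0.176), or any 1 of the 4 arrays (Robo1, Robo4 and Plxna3, up to 0.0855, 0.114 and 0.164). Of 5 Hox genes bright enough to test 1 passed: Hoxa5 was at least 2.12-fold higher in the AV junction (214.5 ± 9.99 against 10.2 ± 0.709, adjusted p = 0.00404). The Hox list did not pass (adjusted p = 0.16).

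Afp, Ttr and Alb were higher in the AV junction. The choice of scaling among those tried does not account for Afp, whose fitted log2 fold was 6.24 or more with quantile normalisation and median scaling. Afp was at background in the ventricular region, so that size is not exact. Both scalings moved folds by little against it, so this test could hardly have come out otherwise. Ttr and Alb were not part of the test. The 9 other hepatic and yolk sac genes tested had a median log2 fold of 0.611 (95% bootstrap interval −0.581 to 1.38, limma's camera, adjusted p = 0.209), and they went both ways. Ambp, at least 1.88-fold higher (no pass without ventricular array 1b), and Rbp4 at 1.38 passed. F2, Itih2 and Serpinf1 gave 0.86, 0.69 and 0.61 without passing. Dlk1, Mttp, Amn and Hnf4a gave −0.70, −0.58, −0.48 and −0.37 without passing, and another tested probe set of Hnf4a gave 0.23. Adjusted over the list alone, 5 were higher and 1 lower. Of the list's 27 genes on the array the rest were too dim to test: Apom read 186 and 175 on the AV arrays against 6.71 and 5.37, and a probe set of Apoa1 103 and 117 against 11.7 and 10.7, but Apob 42.6 and 94.9 against 84.8 and 59.4, and Fgb 16.4 or less on all 4. Cells of the liver bud or yolk sac carried over with the junction might be a source, and expression by cells of the junction itself was not tested, so the 2 cannot be told apart by these genes.

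Of 16 erythroid genes tested 11 were lower in the AV junction (8 with median scaling). The choice of scaling among those tried does not account for this, as the list's median stayed at −0.735 or lower with quantile normalisation and median scaling. Both scalings moved folds by little against its size, so this test could hardly have come out otherwise. A candidate explanation is more blood in the ventricular tissue as dissected: of 24 further erythroid genes 1 was higher, 10 were lower and 13 did not pass, with a median of −0.559 (95% bootstrap interval −0.949 to −0.43, limma's camera, adjusted p = 5.05e-06, and adjusted p = 0.191 with an estimated correlation). Ermap gave −1.70 and Slc25a37 −1.60, although Aqp1 rose by 1.14 (adjusted p = 0.0308, 1 of 2 ventricular arrays above background, up to 0.103 without either AV array or ventricular array 1a). Whether the share of blood differs between the regions in the living heart or only after dissection stays open and was not tested.

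Most ventricular chamber genes tested (16 of 21) were lower in the AV junction. The choice of scaling among those tried does not account for this, since the list's median stayed at −1.01 or lower with quantile normalisation and median scaling. Both scalings moved folds by little against its size, so this test could hardly have come out otherwise. A lower share of cardiomyocytes as the whole cause is argued against, on these arrays only. The 19 cardiomyocyte genes not tied to a chamber had a median of −0.421 (95% bootstrap interval −0.559 to −0.088), above the chamber list's −1.17 (−1.69 to −0.918). Both intervals treat genes as independent, while the estimated correlations within the lists were 0.36 and 0.19, so they may be too narrow. The 19 genes did fall in part, 7 lower, 0 higher and 12 not passing (limma's camera, adjusted p = 0.00557, and 0.582 with an estimated correlation), so a lower share may still account for part. A hypothesis that remains is a regional difference within cardiomyocytes, which arrays taken as 1 pool per region do not test. It is not the only one left. Of 12 atrial genes tested 6 were higher and 2 lower in the AV junction, and the mix of cardiomyocytes in each pool was not tested.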
